A study of Mus musculus with 6 samples.

How the data were processed

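Liver RNA of 6 female mice aged 8 weeks and fed chow was measured on Affymetrix expression arrays, 1 mouse per array, with 3 C57BL/6J mice and 3 mice of the congenic strain B6.C3H-6T. Per the labels' protocols, tissue was kept in RNAlater and total RNA was taken up in TRIzol and checked on a Bioanalyzer. It was copied from an oligo(dT) primer carrying a T7 promoter, then amplified and biotin-labelled by in vitro transcription, and the images were quantified with the scanner's operating software, version 1.2. Because priming starts at the poly(A) tail, a probe set reads mainly the 3' part of a transcript, and a sequence difference between strains under its probes can change its signal. The deposited values are log2 expression values, 1 per probe set and array, made with RMA from the affy package per the submitters' processing notes. The versions of RMA and affy, the array annotation used and any later step were not given in the sources used here. The log2 scale was checked on the values, which ran from about 3 to 15 on each array. No sample was pooled, no technical repeat was made, and no batch or scan date was given for the arrays used here. The sample titles give each mouse a pedigree number of its own, and the sources do not say whether these numbers mark litters or pair mice across the strains. Replicate numbers follow the order of the samples' accessions and only name a mouse.

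The table held 45101 probe sets, and 64 control probe sets were left out, so that 45037 were tested. Probe sets were named through the platform annotation given with the series, with symbols updated through the gene identifier to a RefSeq gene table of assembly GRCm38.p6. A single gene was paired with 34945 of the tested probe sets, several genes with 932, and 9160 had no gene in that table and are unnamed here. Of 18194 genes with a probe set of their own, 18032 were found in the gene table, 992 of them on chromosome 6. The gene table was used only for names, chromosomes and the order of genes, since no genome build was named for the array, and no coordinates are given. Each gene was represented by its probe set with the highest mean over all 6 arrays, a choice that does not use the groups, and other probe sets of the gene were then compared with it.

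Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate) on the deposited log2 values of all 6 arrays, with no filter on dim probe sets. Differences are B6.C3H-6T minus C57BL/6J. P-values were adjusted by the Benjamini-Hochberg method over all probe sets or over all genes, with 0.05 as the threshold. The share of called genes on chromosome 6 was compared with the share among tested genes of known chromosome by a two-sided Fisher's exact test, their direction by a two-sided exact binomial test, and their place by Fisher's exact tests over 360 bins of 50 consecutive tested genes. Gene lists, 24 for pathways and 16 for cell type markers, were written from general knowledge of liver before the data were examined. They were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over all 40 lists, and again with a correlation estimated from the data and with fry. Members were also adjusted over the list alone. List members without a probe set of their own were not analysed here. List means per array were compared by a two-sided exact permutation test, which with 3 against 3 arrays cannot give a p below 0.1. RNA quality was compared as the difference between 3' and 5' control probe sets of Actb and Gapdh.

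The genes named in the text were set by a rule. It takes up to 12 called genes with the largest rise and 12 with the largest fall whose groups do not overlap, or, where fewer than 5 passed in a direction, the 10 of that direction with the smallest p. It adds 11 fixed genes whatever their values (Igf1, Igfals, Igfbp1, Igfbp2, Igfbp3, Ghr, Socs2, Stat5b, Pparg, Alox5 and Ghrhr), up to 4 members of each list, those called over all genes first and then those of smallest p, and up to 15 called genes of chromosome 6. Other genes are named only where a count is small or a test names them, and the text then says that they were chosen after their values were seen.

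The fit was tested on simulated data for the comparison of the strains, with 200 changed probe sets among 45037 in each of 20 runs and independent probe sets. It recovered 86.0% of changes of 0.5, 99.8% of changes of 1 and 100% of changes of 2 on the log2 scale, and 6.81% of its calls were false. Lists shifted by 0.3 in a simulation of 18194 genes were called in 20 of 20 runs in each direction, and the unshifted lists were called in 1 of 760 tests. Real genes are correlated between mice, which this simulation leaves out. Its changed probe sets were also drawn at random from outside the lists, so these rates are averages over all spreads. A gene that varies more between mice can differ by more than 1 without passing, as Elovl3 does below. The alternatives tried were renewed quantile normalization, centring of each array on its median, removal of dim probe sets, a variance trend with robust estimation, no moderation of the variance, another threshold, a minimum size of change, other probe set rules, removal of chromosome 6, other bin sizes, other list tests, and leaving out each array in turn. The number of arrays limits the precision of every value.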

Results

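Gene expression was measured in the liver of 3 C57BL/6J mice and of 3 mice of B6.C3H-6T, a strain congenic on the C57BL/6J background that carries C3H DNA on chromosome 6 and is described in the series as having low serum IGF-1. All mice were females of 8 weeks on chow, and each array held the RNA of 1 mouse. Array medians lay between 6.07 and 6.11 on the log2 scale. Correlations between arrays ran from 0.994 to 0.997 over all probe sets, which are not independent replicates. The first principal component took 37.3% of the variance and placed the B6.C3H-6T arrays on one side and the C57BL/6J arrays on the other. B6.C3H-6T replicate 2 lay farthest out, at 27.3, and B6.C3H-6T replicate 3 nearest to the other strain, at 2.29. The latter array correlated slightly more with the C57BL/6J arrays (mean 0.9964) than with its own strain (mean 0.9962). The second component took 24.0% of the variance and did not separate the strains. The 3' minus 5' signal of Actb was 0.60 ± 0.01 (SD) in C57BL/6J and 0.60 ± 0.09 in B6.C3H-6T (two-sided exact permutation test, p = 1), and that of Gapdh was 0.16 ± 0.02 and 0.17 ± 0.04 (exact permutation p = 0.8, with 0.1 as the smallest p possible).

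The first comparison asked which liver transcripts differ between the strains. In B6.C3H-6T, 11 genes fell and 2 rose at an adjusted p under 0.05, out of 18194 genes. The largest falls among them were in 2 genes near the end of the X chromosome. Mid1, which encodes a microtubule-associated ubiquitin ligase, fell by 1.90 ± 0.13 (log2 difference ± SE, 3 mice per strain, 3.72-fold; limma adjusted p = 0.0023). Erdr1 fell by 1.77 ± 0.14 (adjusted p = 0.00269). Bid, a gene of the apoptosis pathway on chromosome 6, fell by 1.63 ± 0.14, from 8.26 to 6.62 (adjusted p = 0.00421). Serpina12, which encodes the adipokine vaspin, fell by 1.24 ± 0.14, and Fitm1, which belongs to a family of genes for fat storage proteins, fell by 0.77 ± 0.08. The argininosuccinate synthase gene Ass1 of the urea cycle rose by 0.87 ± 0.12, from 8.35 to 9.23 (adjusted p = 0.0496), and the RIKEN transcript 1810008I18Rik rose by 0.62 ± 0.07.

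Tgoln1, a gene for a protein of the trans-Golgi network, decreased by 1.10 ± 0.12, and Plekha8, which encodes a glycolipid transfer protein, decreased by 0.99 ± 0.12. Ift122, a gene of intraflagellar transport, decreased by 0.91 ± 0.07, and the small nucleolar RNA host gene Snhg1 decreased by 0.81 ± 0.07. The annexin gene Anxa4 decreased by 0.62 ± 0.06 and Tpra1 decreased by 0.61 ± 0.06. The adjusted p of these 6 genes ran from 0.0023 for Ift122 to 0.0354 for Plekha8. All 4 other probe sets of Snhg1 and all 3 of Tgoln1 were lower at an unadjusted p under 0.05. So were the single others of Erdr1, Serpina12, Plekha8 and Ift122, and 1 of 2 others of Bid. Neither of the 2 other probe sets of Mid1 was lower, and neither of those of Anxa4, of which 1 was higher by 0.23 ± 0.07. Fitm1, Tpra1, Ass1 and 1810008I18Rik had no other probe set paired with that gene alone, so each of these calls rests on 1 probe set. Probe sets paired with several genes were not compared. Since only 2 rises passed, the 8 genes with the next smallest p were named by the rule, and none of them passed. Trex2 differed by 0.43, the mTOR inhibitor gene Ddit4 by 0.87, and Klf15, a transcription factor gene of amino acid and glucose metabolism, by 0.51. Tmem254a, the sulfotransferase gene Sult1d1 and Atp6v0e2 each differed by 0.43. The hepatic transcription factor gene Foxa2 differed by 0.47 and Cntn4 by 0.31, and adjusted p ran from 0.108 for Trex2 to 0.177 for Cntn4. Of these 8, Ddit4 passed without B6.C3H-6T replicate 1 (adjusted p = 0.0367).

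**Figure D1:**
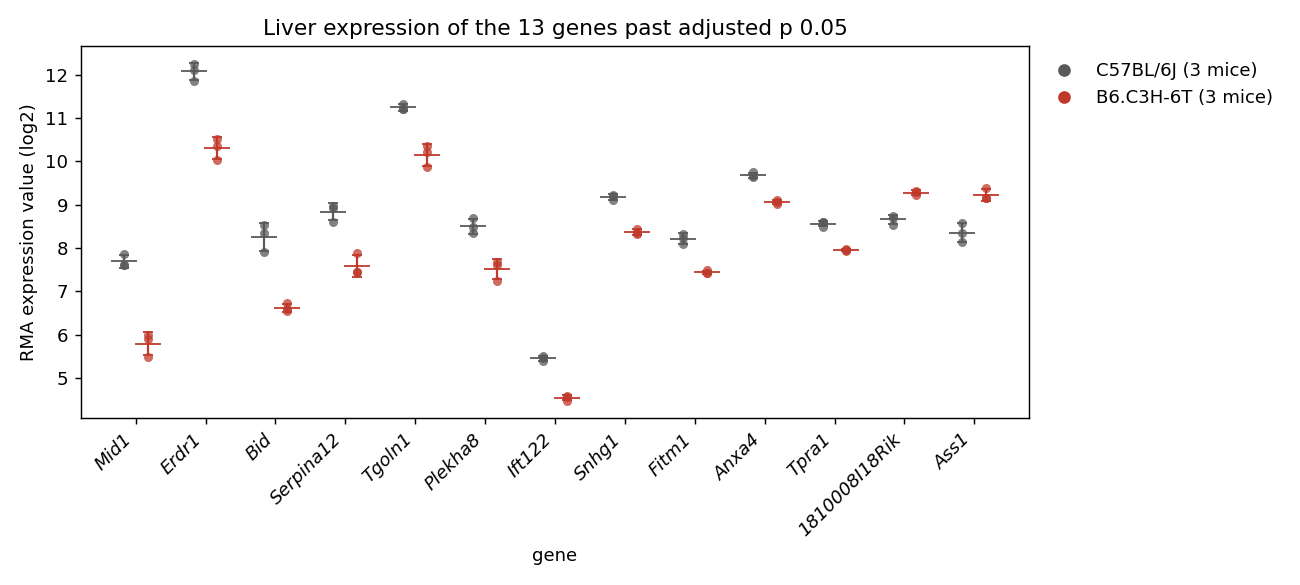
RMA expression values on a log2 axis of the 13 genes past an adjusted p of 0.05, with points for the 3 mice of each strain and bars for the mean ± SD. The values of the strains do not overlap for any of the 13 genes, from Mid1 (7.69 in C57BL/6J and 5.79 in B6.C3H-6T) to Ass1 (8.35 and 9.23).

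Over probe sets, 26 of 45037 passed, 21 lower and 5 higher, and 4755 had an unadjusted p under 0.05. Of the 18194 genes 2209 had an unadjusted p under 0.05, which is the background for the counts of list members below. The strains did not overlap at 17.8% of all genes, against the 10% that chance gives. Of the 13 called genes, Ass1 missed the threshold when adjusted over all probe sets (adjusted p = 0.0554) and the other 12 passed. Some genes were called only through probe sets that did not represent them. Of the phosphatidylserine decarboxylase pseudogene Pisd-ps3, 3 probe sets were higher by 1.96 ± 0.08, 0.92 ± 0.06 and 0.87 ± 0.11. The probe set that represented this gene differed by 0.19 ± 0.07 (adjusted p = 0.361). A probe set of the autophagy gene Atg7 on chromosome 6 was lower by a difference of -0.85 ± 0.10 (adjusted p = 0.0206). The lowest of 8 unnamed probe sets differed by -2.70 ± 0.10. These were chosen after their values were seen. Of the 13 genes, Mid1, Erdr1, Bid, Ift122 and Snhg1 passed without each array in turn. Of these, however, Mid1 and Snhg1 lost the call when the probe set of median p represented each gene. Erdr1 and Ift122 lost it without probe sets ending in _x_at or _s_at. Fitm1 missed the threshold without B6.C3H-6T replicate 2 (adjusted p = 0.0555) and Tgoln1 without C57BL/6J replicate 2 or 3 (0.0918 and 0.113). Serpina12 missed it without either of these C57BL/6J arrays or B6.C3H-6T replicate 1 or 3 (0.0523 to 0.151). Anxa4 missed it without either of them or B6.C3H-6T replicate 2 or 3 (0.0505 to 0.113). Plekha8 and Ass1 missed it without each array but C57BL/6J replicate 1 (0.0505 to 0.270 and 0.0736 to 0.264). Tpra1 and 1810008I18Rik missed it without each array in turn (0.0505 to 0.0831 and 0.0538 to 0.150). The gene count was 6 without C57BL/6J replicate 2, 6 without C57BL/6J replicate 3 and 7 without B6.C3H-6T replicate 2. It was 0 in a linear fit in limma without moderated variances, where 1746 genes had an unadjusted p under 0.05.

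The second comparison asked whether changed genes lie on chromosome 6, which carries the C3H DNA of the congenic strain. The labels do not give the limits of the C3H segment, so the whole chromosome was compared, and called genes may lie outside the segment. Bid, Tgoln1, Plekha8, Ift122, Anxa4 and Tpra1 lie on chromosome 6, so that 6 of the 13 called genes (46.2%) were on a chromosome that holds 5.50% of the tested genes. The 8 unnamed called probe sets, which hold the smallest p of all, and those of Pisd-ps3 have no known chromosome and could not enter this share. The odds ratio was 14.8 (95% interval 4.10 to 51.6; two-sided Fisher's exact p = 3.36e-05). All 6 were lower in B6.C3H-6T (two-sided exact binomial p = 0.0312), against 5 lower and 2 higher elsewhere, a difference between the chromosomes that Fisher's exact test did not separate (p = 0.462). Fewer genes of chromosome 6 were called without each array in turn, all of them lower, with a binomial p of 0.0625 without C57BL/6J replicate 1, 0.5 without C57BL/6J replicate 2 or 3, 0.25 without B6.C3H-6T replicate 2 and 0.125 without either other. A wider set, chosen after seeing the data and made of genes at an unadjusted p under 0.01, held 58 of 992 genes of chromosome 6 (5.85%) and 549 of 17039 others (3.22%; Fisher's exact p = 3.95e-05). In that set 42 genes of chromosome 6 were lower and 16 higher, while elsewhere 296 were lower and 253 higher (Fisher's exact p = 0.00795 for the difference in direction).

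The 6 genes were spread over 5 of the 20 bins of chromosome 6, and most genes of the chromosome were close to 0, with a median difference of 0.01. None of the 360 bins passed by Fisher's exact test with Benjamini-Hochberg adjustment. The 2 bins with the smallest p were the stretch of chromosome 6 from Tgfa to 4933427D06Rik, with Anxa4 and Tpra1, and the end of the X chromosome, with Mid1 and Erdr1 (adjusted p = 0.186 each). With genes called at an adjusted p under 0.10, the bin from Ogg1 to Zfp637 passed (adjusted p = 0.00928), through Pparg, Ift122 and Marchf8, all lower, the last of which was named after its value was seen. With bins of 25 genes the end of the X chromosome from Ofd1 to Erdr1, a last bin of 17 genes, passed (adjusted p = 0.0468). Pparg, the nuclear receptor gene of fat storage, was lower by a difference of -0.66 ± 0.10 (7.43 to 6.77, adjusted p = 0.0744). Among other chromosome 6 genes fixed by name, the lipoxygenase gene Alox5 differed by 0.23 ± 0.08 (adjusted p = 0.345) and the growth hormone releasing hormone receptor gene Ghrhr by -0.00 ± 0.06. The fixed list of chromosome 6 genes of metabolic and bone interest had 14 members higher and 12 lower. Its median was 0.01, its mean -0.03 and its camera test downward (adjusted p = 0.519). Of its members 2 passed adjusted over the list alone, Pparg and the chondrocyte transcription factor gene Sox5 (-0.30 ± 0.07), against 0 over all genes in limma, where 5 had an unadjusted p under 0.05.

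**Figure D2:**
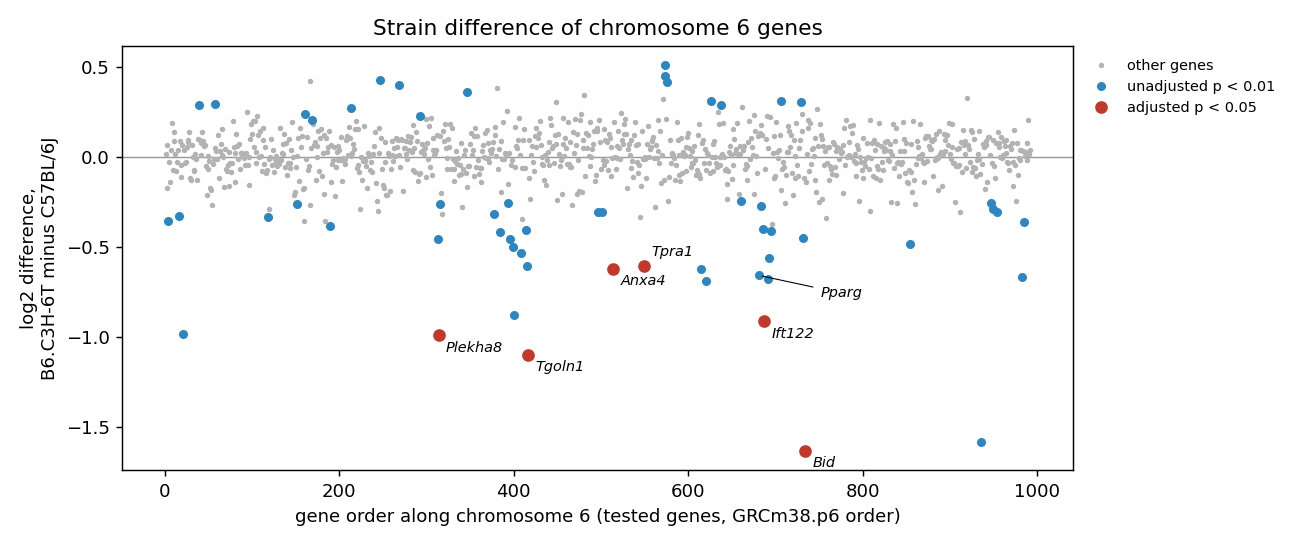
Log2 difference between the strains (B6.C3H-6T minus C57BL/6J, 3 mice each) of the 992 tested genes of chromosome 6, in gene order of assembly GRCm38.p6, with genes past an adjusted p of 0.05 in red and those at an unadjusted p under 0.01 in blue. The 6 red genes, from Plekha8 to Bid, lie between -1.63 and -0.61, and the median of all genes shown is 0.01.

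The third comparison followed the growth hormone and IGF-1 axis, since circulating IGF-1 is made mostly by liver under growth hormone control. Igf1 differed by -0.28 ± 0.09, from 12.50 ± 0.14 to 12.22 ± 0.13 (mean ± SD, 3 mice per strain), with no overlap between the strains, but did not pass over all genes (limma adjusted p = 0.325; -0.34 to -0.20 without 1 array). All 3 other probe sets of Igf1 were lower at an unadjusted p under 0.05. Igfals, which encodes the subunit that stabilizes circulating IGF-1 complexes, differed by -0.30 ± 0.12 (adjusted p = 0.383; -0.40 to -0.16 without 1 array). The binding protein genes Igfbp1, Igfbp2 and Igfbp3 differed by -0.22 ± 0.13, -0.27 ± 0.22 and 0.19 ± 0.12. Leaving out 1 array moved these differences from -0.33 to -0.12 for Igfbp1, from -0.49 to -0.01 for Igfbp2 and from 0.09 to 0.30 for Igfbp3, and none passed. The growth hormone receptor gene Ghr differed by 0.09 ± 0.09 (0.02 to 0.16 without 1 array), its signal transducer gene Stat5b by -0.00 ± 0.10 (-0.09 to 0.06) and its feedback inhibitor gene Socs2 by -0.38 ± 0.19 (adjusted p = 0.466; -0.55 to -0.16 without 1 array). Stat5a differed by -0.61 ± 0.13 (adjusted p = 0.196), Cish, another feedback inhibitor gene, by 0.55 ± 0.15 (adjusted p = 0.269) and Stc2 by 0.23 ± 0.07.

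As a list, the axis did not pass the test. Of 29 measured members 13 were higher and 16 lower, the median was -0.00 and the mean -0.05 (camera adjusted p = 0.468, and adjusted p = 0.802 with an estimated correlation). Stat5a was the 1 member to pass adjusted over the list alone, and 0 passed over all genes in limma, where 6 had an unadjusted p under 0.05. Genes with sex-biased expression in liver, which depend on the pattern of growth hormone release, went both ways. The male-biased list had 15 of 28 members lower, a median of -0.05 and a mean of -0.20 (camera adjusted p = 0.04996, and adjusted p = 0.609 with an estimated correlation). The list's mean per array overlapped between the strains (two-sided exact permutation p = 0.2). Its members past the threshold adjusted over the list alone numbered 4: Elovl3 (-1.68 ± 0.35), a gene of fatty acid elongation, the organic anion transporter gene Slco1a1 (-1.59 ± 0.42), Gna12 (-0.31 ± 0.08) and Serpina12. Serpina12 was the only one to pass over all genes. Without 1 array that count was 11 (C57BL/6J replicate 1), 1 (C57BL/6J replicate 2 or 3), 7 (B6.C3H-6T replicate 1) or 2 (B6.C3H-6T replicate 2). The list's call was lost without C57BL/6J replicate 2 (0.0750), C57BL/6J replicate 3 (0.244), B6.C3H-6T replicate 2 (0.0873) or B6.C3H-6T replicate 3 (0.123). It was also lost after centring of the arrays (0.103), among the brighter probe sets (0.272), with the mean of all probe sets (0.128) and with fry (0.384). Nor was this list among those called with the probe set of median p or without probe sets ending in _x_at or _s_at. The female-biased list had 19 of 29 members higher and a median of 0.08 (camera adjusted p = 0.468). Of its members 10 passed adjusted over the list alone, 5 higher and 5 lower, against 0 over all genes in limma, where 12 had an unadjusted p under 0.05. Sult2a2 (0.79 ± 0.20) and Cyp2b9 (0.26 ± 0.07) were among the higher, and Sult3a1 (-0.67 ± 0.11) and Acot4 (-0.48 ± 0.14) among the lower. Sult3a1 passed over all genes without C57BL/6J replicate 1 (adjusted p = 0.0434). Without 1 array this count was 3 (C57BL/6J replicate 2), 1 (C57BL/6J replicate 3 or B6.C3H-6T replicate 2) or 5 (B6.C3H-6T replicate 3).

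**Figure D3:**
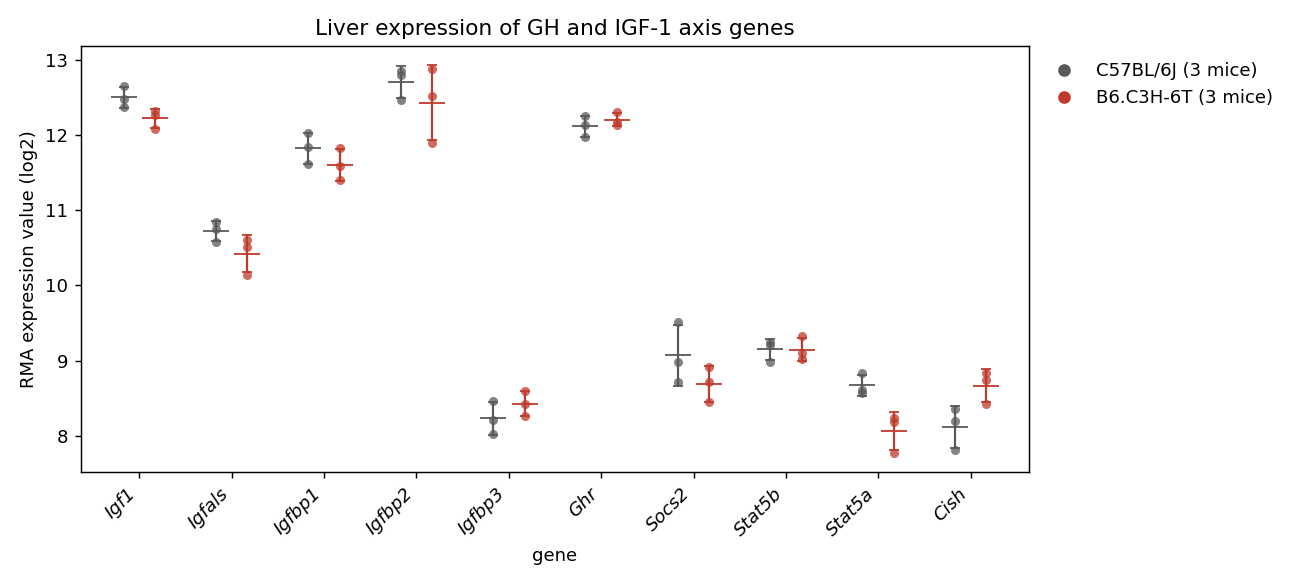
RMA expression values on a log2 axis of 10 genes of the growth hormone and IGF-1 axis, with points for the 3 mice of each strain and bars for the mean ± SD. Igf1 has a mean of 12.50 in C57BL/6J and 12.22 in B6.C3H-6T, and Stat5a of 8.67 and 8.07, and neither passed over all genes.

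The fourth comparison took the other fixed lists, and the widest shifts were in lipid metabolism. Targets of PPAR alpha and genes of fatty acid oxidation were lower in B6.C3H-6T in 37 of 38 cases, with a median of -0.31 (camera adjusted p = 5.54e-19, but adjusted p = 0.572 with an estimated correlation). Those named by the rule were the acyl-CoA thioesterase gene Acot1 (-1.34 ± 0.27), the pantetheinase gene Vnn1 (-1.03 ± 0.19), the pyruvate dehydrogenase kinase gene Pdk4 on chromosome 6 (-0.98 ± 0.20) and the peroxisomal gene Pex11a (-0.84 ± 0.15). Adjusted over the list alone 17 members passed, all lower, against 0 over all genes in limma, where 21 had an unadjusted p under 0.05. The genes of fatty acid synthesis were higher in 29 of 30 cases, with a median of 0.33 (camera adjusted p = 3.06e-09, but adjusted p = 0.572 with an estimated correlation). They included the phosphatidate phosphatase gene Lpin1 (1.22 ± 0.28), the acetyl-CoA synthetase gene Acss2 (0.71 ± 0.17), the acetyl-CoA carboxylase gene Acacb (0.54 ± 0.14, and 0.36 to 0.64 without 1 array), the stearoyl-CoA desaturase gene Scd1 (0.33 ± 0.10) and Thrsp (1.36 ± 0.41, and 0.82 to 1.69 without 1 array). Of the 30, 7 passed adjusted over the list alone, all higher, against 0 over all genes in limma, where 15 had an unadjusted p under 0.05.

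The mean of the PPAR alpha list was 11.26 ± 0.13 (SD) in C57BL/6J and 10.89 ± 0.21 in B6.C3H-6T, and that of fatty acid synthesis 10.48 ± 0.09 and 10.90 ± 0.32. Neither overlapped between the strains (two-sided exact permutation p = 0.1 each, the smallest possible). Some lists that did not pass camera, such as kidney and adipocyte markers, reached the same p. B6.C3H-6T replicate 2 stood apart in both lists, and without it the mean difference of fatty acid synthesis was 0.24 in place of 0.43. The 17 PPAR alpha members past the threshold became 5 without C57BL/6J replicate 2 or 3, 6 without B6.C3H-6T replicate 2 and 27 without B6.C3H-6T replicate 1. The 7 of fatty acid synthesis became 0 without C57BL/6J replicate 2 or 3, 12 without C57BL/6J replicate 1 and 16 without B6.C3H-6T replicate 3.

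Genes of glucose production and glycogen were higher in 25 of 32 cases, with a median of 0.20 (camera adjusted p = 0.000517, but adjusted p = 0.572 with an estimated correlation). The aminotransferase genes Got1 (0.74 ± 0.18) and Tat (0.42 ± 0.09) and the transcription factor genes Foxa2 (0.47 ± 0.09) and Foxo3 (0.36 ± 0.09) were among 7 higher and 2 lower members past the threshold adjusted over the list alone. Over all genes 0 passed in limma, where 15 had an unadjusted p under 0.05. The count over the list was 1 without C57BL/6J replicate 2 and 2 without C57BL/6J replicate 3, and without B6.C3H-6T replicate 2 the list's mean difference was 0.11 in place of 0.17. Genes of oxidative phosphorylation were higher in 50 of 58 cases by a small amount, with a median of 0.10 (camera adjusted p = 0.000211, but adjusted p = 0.802 with an estimated correlation). The examples Cyc1 (0.22 ± 0.08), Ndufs8 (0.20 ± 0.08) and Atp5d (0.19 ± 0.08) did not pass. The list's mean per array overlapped between the strains (two-sided exact permutation p = 0.3). The mean difference of this list was 0.09, and it was 0.04 without B6.C3H-6T replicate 2, where the call was lost (adjusted p = 0.193), and 0.13 without B6.C3H-6T replicate 3. PPAR gamma and lipid droplet genes were lower in 17 of 28 cases, with a median of -0.05 (camera adjusted p = 0.0176, but adjusted p = 0.572 with an estimated correlation). G0s2 (-0.90 ± 0.22), which encodes an inhibitor of triglyceride lipase, and Pparg passed adjusted over the list alone. Over all genes 0 passed in limma, where 13 had an unadjusted p under 0.05. Plin5 differed by -0.29 ± 0.08 and Vldlr by 0.25 ± 0.08. The call of this list was lost without chromosome 6 genes (adjusted p = 0.0980), without C57BL/6J replicate 2 (0.0503) and without B6.C3H-6T replicate 3 (0.1003). Genes of vitamin D, retinoid and iron handling were higher in 22 of 27 cases, with a median of 0.11 (camera adjusted p = 0.00639, but adjusted p = 0.572 with an estimated correlation). The hepcidin gene Hamp2 differed by 0.77 ± 0.18 and the retinoic acid hydroxylase gene Cyp26a1 by 0.81 ± 0.25. None passed, with 0 adjusted over the list alone and 0 over all genes in limma, where 6 had an unadjusted p under 0.05.

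**Figure D4:**
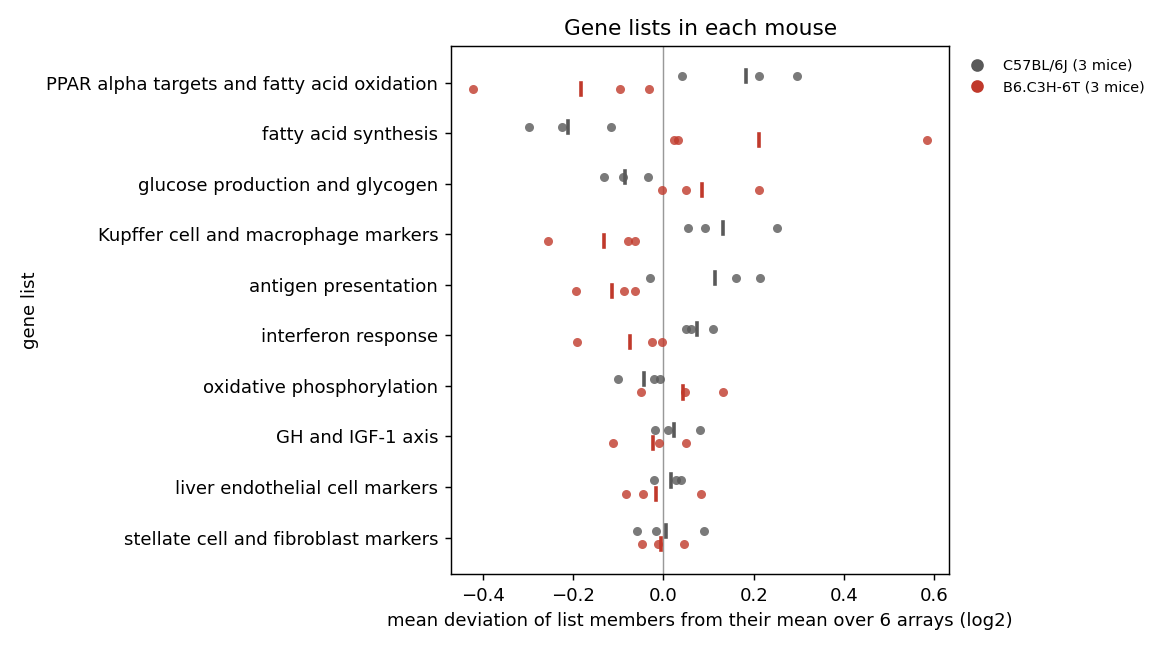
Mean deviation of the members of 10 fixed gene lists from their mean over the 6 arrays (log2), with a point for each mouse and a bar for the mean of the 3 mice of a strain. PPAR alpha targets lie between 0.04 and 0.30 in C57BL/6J and between -0.42 and -0.03 in B6.C3H-6T, while endothelial and stellate cell markers overlap.

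Of the lists of immune genes and cells, 3 passed the preset test, each lower in B6.C3H-6T. Markers of Kupffer cells, the resident macrophages of liver, were lower in 17 of 18 cases, with a median of -0.26 (camera adjusted p = 1.75e-10, but adjusted p = 0.572 with an estimated correlation). Aif1 (-0.48 ± 0.11), Timd4 (-0.47 ± 0.11), Tyrobp (-0.34 ± 0.09) and C1qb (-0.27 ± 0.07) were among 8 members past the threshold adjusted over the list alone, all lower. Over all genes 0 passed in limma, where 12 had an unadjusted p under 0.05. Genes of antigen presentation were lower in 12 of 16 cases, with a median of -0.18 (camera adjusted p = 1.15e-05, but adjusted p = 0.572 with an estimated correlation). The class II genes H2-Aa (-0.72 ± 0.15), H2-Ab1 (-0.59 ± 0.15) and H2-DMa (-0.44 ± 0.12) and the invariant chain gene Cd74 (-0.58 ± 0.13) were among 6 that passed adjusted over the list alone, all lower. Over all genes 0 passed in limma, where 8 had an unadjusted p under 0.05. Genes of the interferon response were lower in 36 of 43 cases, with a median of -0.15 (camera adjusted p = 1.69e-07, but adjusted p = 0.572 with an estimated correlation). Ifit2 differed by -0.39 ± 0.09, Igtp by -0.33 ± 0.08, Irgm2 by -0.32 ± 0.09 and Trim30a by -0.25 ± 0.07. Of this list 0 passed adjusted over the list alone, and 0 over all genes in limma, where 15 had an unadjusted p under 0.05.

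List means did not overlap between the strains for any of these 3 lists (two-sided exact permutation p = 0.1 each, the smallest possible). This was not particular to called lists. The means of erythroid, adipocyte and kidney markers and of the chromosome 6 interest list did not overlap either, and none of these passed camera. The 8 Kupffer cell markers past the threshold became 0 without C57BL/6J replicate 2 and 2 without B6.C3H-6T replicate 2. The 6 of antigen presentation became 0 without C57BL/6J replicate 1 or 2 and 2 without B6.C3H-6T replicate 2. Without this last array the mean difference of the interferon list was -0.09 in place of -0.15. Markers of other cell types were measured beside them. Endothelial cell markers had 11 of 16 members lower and a median of -0.05 (camera adjusted p = 0.360), and passed, lower, without B6.C3H-6T replicate 1 (0.0244). Stellate cell and fibroblast markers had a median of 0.01 and a mean of -0.01 with a downward test (adjusted p = 0.514). T and NK cell markers had a median of 0.01 and a mean of -0.00 with a downward test (adjusted p = 0.842). B cell and plasma cell markers had a median of -0.09 (adjusted p = 0.140, but 0.0322 without B6.C3H-6T replicate 1) and neutrophil markers a median of 0.11 (adjusted p = 0.349). Hepatocyte markers had a median of 0.02 (adjusted p = 0.364). Periportal hepatocyte markers, which hold Ass1, had a median of 0.12 (adjusted p = 0.0619) and pericentral hepatocyte markers a median of -0.02 (adjusted p = 0.514). The periportal list passed after centring of the arrays (0.0342), among the brighter probe sets (0.0478), with the mean of all probe sets (0.0491) and without C57BL/6J replicate 1 (0.0116) or B6.C3H-6T replicate 2 (0.0140). Pancreatic acinar cell markers passed the preset test with 11 of 13 members higher and a median of 0.12 (camera adjusted p = 0.0393, but adjusted p = 0.572 with an estimated correlation), with Cela3b at 7.31 and 7.49. That call was lost without chromosome 6 genes (adjusted p = 0.139), after renewed quantile normalization (0.0781), and among the brighter probe sets (0.649). It was also lost without C57BL/6J replicate 2 (0.0750), B6.C3H-6T replicate 1 (0.0537) or B6.C3H-6T replicate 3 (0.143).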

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

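The lists and most alternatives were fixed before the data were examined. Chosen after seeing the data were the wider gene set at an unadjusted p under 0.01, the list members past the threshold without each array, the share with the median p rule, and the direction under settings other than the brighter probe sets, the mean of all probe sets and leaving out 1 array. No paired analysis was made because the sources do not pair the mice. No result reversed. Counts of probe sets ran from 11 to 17 without 1 array (26 with all) and counts of genes from 6 to 15 (13 with all), where fewer arrays enter. Without moderated variances 0 probe sets and 0 genes passed in limma's ordinary linear fit, with 3841 and 1746 at an unadjusted p under 0.05. That fit lacks the 4.96 prior degrees of freedom that moderation added, which makes small p-values harder to reach. How far this accounts for the loss was not tested. At an adjusted p under 0.10, 45 probe sets and 21 genes passed, as the looser threshold implies. Without chromosome 6, 14 probe sets passed: 8 of the 26 were removed, and 4 others missed the threshold when p-values were adjusted over the rest. Renewed quantile normalization, centring, removal of dim probe sets, a variance trend, the size minimum and the other probe set rules gave 21 to 32 probe sets and 9 to 18 genes. The same 26 probe sets and 13 genes remained among the 32 and 18 called with the variance trend. Plekha8 missed the threshold after renewed quantile normalization (adjusted p = 0.0530) and Ass1 after centring (adjusted p = 0.0520), and the cause was not tested. Ift122, at 5.46 and 4.55, was removed with the dim probe sets.

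The share of called genes on chromosome 6 stayed above that of tested genes, by Fisher's exact test, under all alternatives run, from 9% to 50%, and from 15.5% to 40% without 1 array. The 200 genes of smallest p stood in for called genes where fewer than 10 passed: without moderation, with the probe set of median p (16.6%), and without C57BL/6J replicate 2, C57BL/6J replicate 3 or B6.C3H-6T replicate 2. In the wider gene set it was 9.56%. Called genes of chromosome 6 were 100% lower under each alternative that called any, and none was called without moderation. Their exact binomial p was 0.0625 (100% of 5) after renewed quantile normalization, among the brighter probe sets, with the mean of all probe sets and without probe sets ending in _x_at or _s_at. It was 0.125 with the probe set of median p (100% of 4) and 0.0625 to 0.5 without 1 array (100% to 100%), as fewer genes were called. In the wider set 42 were lower and 16 higher. With bins of 25 genes 1 bin passed and with genes at an adjusted p under 0.10 also 1, against 0. The first was the last bin of the X chromosome, with 17 genes in place of 67 and the same called genes, Mid1 and Erdr1. In the second, Pparg and Marchf8 were called beside Ift122.

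The growth hormone and IGF-1 list passed nowhere, with a mean from -0.08 to -0.00 without 1 array (adjusted p 0.227 to 0.831). Of the fixed lists 11 passed, and 8 to 15 without 1 array, but 0 with a correlation estimated from the data and 0 with fry, where 1 and 6 lists had an unadjusted p under 0.05 and the smallest adjusted p were 0.572 and 0.158. The list calls therefore depend on the preset correlation. Over the named genes under both normalizations, the level filter, the variance trend and leaving out 1 array, 1720 values kept direction and side of the threshold, 35 lost the call and 5 gained it; over the lists, list tests included, these numbers were 467, 39 and 14. A further 8 values of genes changed sign, and 25 list tests changed direction, where neither setting called them. The mean of a list could keep its sign while the direction of its test changed. Outside that count, 13 of the 13 called genes lost the call without moderation, 5 with the probe set of median p, 3 with the mean of all probe sets and 3 without probe sets ending in _x_at or _s_at. The number of arrays limits all of these values, and signal over background was not given for the arrays used here.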

Other observations

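Beyond the lists described in the comparisons, several lists of liver genes held members apart between the strains, although the whole list did not pass with all arrays. The tests of other probe sets, of the fed state, of a single mouse and of non-hepatocyte cells given below were chosen only after the results were seen. The circadian clock list had 19 of 26 members higher and a median of 0.12 (camera adjusted p = 0.103). It passed after renewed quantile normalization (0.0495), after centring of the arrays (0.0404) and without C57BL/6J replicate 1 (0.0183) or B6.C3H-6T replicate 1 (0.00443). Its mean of 0.14 ran from 0.07 to 0.19 without 1 array, with a camera adjusted p of up to 0.512. Adjusted over the list alone 4 passed, namely the deadenylase gene Noct (0.65 ± 0.15), Upp2 (0.81 ± 0.20), Usp2 (0.35 ± 0.10) and, lower, the vasopressin receptor gene Avpr1a (-0.62 ± 0.17). The thyroid hormone list had a median of 0.08 (adjusted p = 0.512). Its members past the threshold adjusted over the list alone numbered 4, with Thrsp and the steroid hydroxylase gene Cyp17a1 (0.88 ± 0.26, and 0.56 to 1.21 without 1 array) higher and Serpina7, which encodes thyroxine-binding globulin (-1.13 ± 0.26), and Gpd2 (-0.37 ± 0.11) lower. In the acute phase list (median 0.05, adjusted p = 0.291) Orm2 (0.49 ± 0.10) and Hamp2 passed adjusted over the list alone. In the unfolded protein and amino acid stress list (median 0.02, adjusted p = 0.364) Ddit4 did, and Chac1 stood at 0.49 ± 0.14 (0.31 to 0.62 without 1 array). In the heat shock list (median 0.06, adjusted p = 0.514) Hspb1 did, at -0.53 ± 0.10, and in the cell cycle list (median -0.00, adjusted p = 0.458) the replication gene Mcm7 did, at -0.40 ± 0.07. In these 6 lists 0 genes passed over all genes in limma, where 7, 6, 8, 7, 4 and 5 had an unadjusted p under 0.05. The lists held 26, 18, 42, 42, 20 and 39 measured members. Of all 18194 genes 2209 had such a p, a share close to that of the cell cycle list. The other lists held larger shares, which were not tested against the share of all genes. Without B6.C3H-6T replicate 1, Noct, Ddit4 and Hspb1 passed over all genes (adjusted p = 0.0266, 0.0367 and 0.0367).

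With all arrays no list of sterol or detoxification genes passed, but 2 did without 1 array. Cholesterol synthesis had 13 of 22 members higher and a median of 0.02 (camera adjusted p = 0.398), with Aacs at 0.63 ± 0.16 and Dhcr7 at 0.35 ± 0.14 (0.19 to 0.50 without 1 array). Without B6.C3H-6T replicate 1 this list passed, with a mean of 0.18 in place of 0.07 (adjusted p = 0.000145), and so did Aacs over all genes (0.0266). The list's mean was 0.001 without B6.C3H-6T replicate 3 and 0.02 without C57BL/6J replicate 1. Bile acid genes had a median of -0.04 (adjusted p = 0.514), with the reductase gene Akr1d1 of chromosome 6 at 0.43 ± 0.13 (0.27 to 0.52 without 1 array). Targets of CAR, PXR and AHR had 26 of 38 members higher and a median of 0.08 (adjusted p = 0.271), and Sult1d1 passed adjusted over the list alone. Glutathione and NRF2 genes had 28 of 38 members higher and a median of 0.05 (adjusted p = 0.241), with Gsta3 at 0.21 ± 0.08 and Gss at -0.32 ± 0.10 (-0.41 to -0.21 without 1 array). Without C57BL/6J replicate 1 this list passed, with a mean of 0.16 in place of 0.09 (adjusted p = 0.0062). Its mean was 0.01 without C57BL/6J replicate 3 (camera adjusted p = 0.972). Arachidonate genes had a median of 0.02, a mean of -0.00 and a downward test (adjusted p = 0.855). Complement and coagulation genes had a median of 0.02, a mean of -0.02 and a downward test (adjusted p = 0.514), with C1qc at -0.31 ± 0.09 and F11 at -0.37 ± 0.11, and passed, lower, without C57BL/6J replicate 1 (mean -0.06, adjusted p = 0.0387). Their mean turned to 0.02 without C57BL/6J replicate 2 and to 0.004 without B6.C3H-6T replicate 2. Of the remaining marker lists, cholangiocyte (median 0.04, adjusted p = 0.514), erythroid (0.01, 0.514), adipocyte (0.07, 0.271), skeletal muscle (0.08, 0.150) and kidney markers (0.09, 0.241) did not pass. Intestine and gallbladder markers had a median of 0.09, a mean of -0.04 and a downward test (adjusted p = 0.855).

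A first pattern was the lower signal of called chromosome 6 genes, since the C3H sequence of the congenic region may weaken binding to probes designed on another strain. The labels do not give the limits of that region, so it is not known which called genes carry C3H sequence. For Bid, Tgoln1, Plekha8 and Ift122 the lower signal was not limited to a single probe set: their 7 other probe sets had a median of -0.49 (-1.05 to -0.13), all 7 lower and 6 of them at an unadjusted p under 0.05, though these 4 genes were set apart from Anxa4 after their values were seen and 1 of the 2 others of Bid was not lower at that p. The median and counts are therefore no independent test. That probe set of Bid and the other one of Ift122 were dim, with means of 4.09 and 4.87. For Anxa4 a sequence effect stays open and fits the values, since the other 2 probe sets were both higher, the highest at 0.23, and for Tpra1 it was not testable with 0 other probe sets. Probe sequences and overlaps between probe sets were not examined, so differences under several probe sets at once also stay open. The biological explanation, that C3H alleles lower these transcripts in liver, stays open as well and was not tested.

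A second pattern was the lower PPAR alpha targets with higher fatty acid synthesis genes, which may follow the state of the mice at dissection. A more fed state of B6.C3H-6T stays open: 12 genes induced in fasting had a median of 0.25 (interquartile range 0.19 to 0.37), 10 of them higher, 8 at an unadjusted p under 0.05, and the 5 not named by rule had a median of 0.23 with 1 lower, which goes against it, but all 12 belong to the fixed lists, 7 of them to the glucose production list already found higher, and Igfbp1 and Irs2 were lower. A single divergent mouse as the whole cause is argued against by the mean of the PPAR alpha list, which stayed between -0.44 and -0.25 without each array. A part due to B6.C3H-6T replicate 2 stays open, since the -0.25 came without it. In the PPAR alpha list it deviated by -0.42, against -0.03 and -0.10 for the other B6.C3H-6T mice. Without it the mean difference of fatty acid synthesis was 0.24 in place of 0.43. A different time of day stays open: the contrast of clock genes of opposite phase differed by 0.0915 (1.75 ± 0.23 in C57BL/6J and 1.84 ± 0.04 in B6.C3H-6T, exact permutation p = 0.8), which is within its spread, while Per1, Per2 and Per3 stood at 0.56 ± 0.21, 0.34 ± 0.13 and 0.42 ± 0.18. An effect of the C3H alleles, directly or through lower IGF-1, stays open and was not tested.

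Another pattern was the lower level of Kupffer cell, antigen presentation and interferon genes. A lower share of all non-hepatocyte cells is argued against by the pooled endothelial and stellate cell markers, whose median was -0.00144 (interquartile range -0.07 to 0.02, 34 genes), although the endothelial list passed, lower, without B6.C3H-6T replicate 1 (mean -0.08). Fewer macrophages may account for part of it: 19 macrophage genes outside the lists, some of them shared with other leukocytes, had a median of -0.20 (interquartile range -0.31 to -0.18), 18 of 19 lower. Of the 18 Kupffer cell markers 4 are in another list, and bulk liver holds these cells by nature, so fewer cells and lower expression per cell stay open together. An effect of the strain's alleles on macrophages was not tested.

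Other splits of the 6 arrays into 3 and 3 number 10, the real one included, which is too few for a share under 0.05. The real split called 26 probe sets, 13 genes and 6 genes of chromosome 6, where the highest of the other splits called 0, 0 and 0, so that 1 of 10 splits gave as many of each. It called 11 lists, while the highest of the others called 17, and 4 of the 10 splits gave as many. The split that put C57BL/6J replicate 2 with B6.C3H-6T replicates 1 and 2 had 5334 probe sets at an unadjusted p under 0.05, more than the 4755 of the real split.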
